A study of Mus musculus with 2 samples.

How the data were processed

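The series measured gene expression in single cells of whole mouse lung after silica was given into the trachea, in wild-type (WT) mice and in mice without the chemokine receptor gene Ccr2 (CCR2KO). Per the labels' protocols, silica was given at 400 mg/kg, and lungs were taken on days 3, 7 and 21. The lungs were digested with an enzyme mix, cells were collected from a density gradient, and each suspension was stained with a hashtag, an antibody that carries a DNA barcode. The stained suspensions were pooled, and 20000 cells were loaded on a microwell cartridge (BD Rhapsody), per the labels' protocols. The labels list 1 library per genotype, so genotype and cartridge are confounded in every comparison.

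The deposited tables hold counts as whole numbers, with 1 gene per line and 1 cell per column, and no normalization. Per the submitters' processing notes, cutadapt 2.10, Bowtie2 2.4.2, R 3.6.3 and the GRCm38 build were used, with no role or order given. Neither the counting rule nor the annotation nor the handling of molecular identifiers is stated. The values themselves are large for a cell. The median nonzero entry was 10, and 21.65% of nonzero entries were 1, so the deposited counts were treated as reads and not as molecules. Intervals and floors made from reads therefore cover counting error only. The authors' column names place each cell under a hashtag or under the word doublet. There were 9 hashtags in the WT table and 8 in the CCR2KO table, and 2 columns with neither kind of name were not used. No label or file says which hashtag stands for which day, or whether a hashtag stands for 1 animal.

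The WT table held 23966 genes and the table of CCR2KO held 23426, of which 22975 were in both; a gene absent from a table was given a count of 0 there. The WT table held 17854 cells with a hashtag and 680 named doublet, with 721704064 reads over both. The CCR2KO table held 15955 and 531, with 624480249 reads. Cells with a hashtag had a median of 25067.5 reads and 1168.5 detected genes in WT, and of 21736 reads and 898 detected genes in CCR2KO. A hashtag had between 1708 and 2208 cells in WT and between 1712 and 2212 in CCR2KO.

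Cells with at least 200 detected genes and at most 25% mitochondrial reads were kept. Doublets were called with Scrublet within each library at an expected rate of 0.06 and left out. These steps left 16786 WT cells and 14792 CCR2KO cells. Counts were scaled to 10000 per cell and log-transformed, and both libraries were clustered together in Scanpy 1.11.5, with 2000 variable genes, 40 principal components, 20 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1.5 and seed 1. Ccr2 was left out of the clustering. Of 35 clusters, 27 took a name from 227 marker genes fixed before the data were examined, 7 of which were not in the tables. A name needed at least 3 markers of a class among the 100 genes with the highest fold in the cluster, and a margin of 1.5 times over the next class. The names give likeness to a type, and 8 clusters went without a class name and are called by number. Cluster 26 was set aside as mixed by a limit on the mean Scrublet score that was chosen after the data were seen; it held 1.13% of WT cells and 0.872% of CCR2KO cells. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.

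Reads were summed per class and hashtag, and CCR2KO was compared with WT by edgeR 4.0.16 with its quasi-likelihood test, filterByExpr, TMM factors and Benjamini-Hochberg adjustment at 0.05. Standard errors (SE) of log2 changes were taken from the change and its F statistic. A hashtag entered a class with at least 10 cells, and a class needed at least 3 such hashtags per genotype. CPM values, reads scaled to the same total in every hashtag, are given as means over hashtags; those of tested genes use totals adjusted by TMM, and those of Ccr2 given with an SD use plain totals. A fold against a genotype whose hashtags were all at 0 is given against a floor of 3 reads over the pooled genotype. A single cell can hold many reads of a gene, so this fold is no bound on the difference in cells or molecules. Shares of cells per class were compared with a two-sided exact permutation test over hashtags, adjusted over all classes tested. The smallest p-value that 9 against 8 hashtags allow is 8.22707e-05. Sets of genes were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and again with an estimated correlation, on 27 gene lists and 34 marker lists fixed before the data were examined. The edgeR step was tested on simulated data with 200 changed genes per class. It recovered 1% of 2-fold and 17% of 4-fold changes in the classical monocyte-like class, and 33% and 67% in the alveolar macrophage-like class.

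The design chosen before the data were examined allowed these tests only where hashtags mark animals, with at least 2 per genotype and day. That condition could not be checked, and the choice to test over hashtags was made after the cell names had been seen. The p-values measure spread between stained suspensions, which may be technical replicates of fewer animals, and days could not be modelled. A standard deviation (SD) over hashtags therefore includes differences between days. The other branch of that design, which calls genes by size from the pooled libraries with no test, was run as an alternative. Comparisons between days were not made.

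The genes named were chosen by a rule fixed before the data were examined. Ccr2 was always named. In classes of at least 200 cells, up to 12 genes higher and 12 lower were taken by size of change, among those with an adjusted p-value under 0.05 and a mean of at least 20 CPM in the higher genotype. Markers that named a class, gene models without a symbol, mitochondrial, ribosomal protein, immunoglobulin and haemoglobin genes were counted and not named. Up to 4 members of a list were named as examples. A gene outside the rule is described where it appears as chosen after its values were seen.

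Alternatives covered stricter and looser cell filters, doublets kept, other clusterings, other denominators, other scalings, gene filters and size limits, cells thinned to 5000 reads, DESeq2 1.42.0, each hashtag left out in turn, and the hashtag number as a block. Equal cell numbers, DESeq2 size factors within edgeR, the hashtags present in both libraries, both size rules on pooled libraries, a clustering without the genes called between genotypes, and same-numbered hashtags as pairs for shares were added after the data were seen. Gene positions come from the GENCODE M21 annotation of GRCm38.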

Results

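Single-cell RNA sequencing was done on lungs of WT and CCR2KO mice after silica, a mineral dust that injures the lung and leads to scarring. Lungs were taken on days 3, 7 and 21. The WT library held 9 hashtagged suspensions (tags) and the CCR2KO library 8. Tags are numbered as in the tables, and the same number in both libraries was not taken as a pair. Reads per tag lay between 63327246 and 94948946 in WT and between 56541715 and 88359317 in CCR2KO. The files do not say which tag holds which day or animal, so days were not compared. Values are means over tags, with ± SD where given, and each p-value measures spread between tagged suspensions, not animals. Each genotype was run on its own cartridge, so a difference between genotypes is also a difference between cartridges. At an equal depth of 5000 reads, WT cells showed 812 ± 68.3 detected genes (n = 9) and CCR2KO cells 665 ± 26.3 (n = 8, exact permutation p = 8.22707e-05). Fewer genes were detected in CCR2KO in each population measured, with a ratio of CCR2KO to WT between 0.785 in monocyte-like cells and 0.9405 in cluster 3, where the exact permutation p was 0.209.

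The first question was whether the receptor that was knocked out was lost. Ccr2, which encodes the receptor that monocytes follow toward the chemokine CCL2, was 75.2 ± 17.6 CPM over all WT cells (n = 9) and 2.73 ± 1.11 CPM over all CCR2KO cells (n = 8). The lowest WT tag had 53.9 CPM and the highest CCR2KO tag 4.43 CPM, from 50208 and 1559 reads in total. The level over all cells also reflects the cell make-up. Monocyte-like cells (6.84% of WT and 1.14% of CCR2KO cells) and cluster 11 were fewer in CCR2KO. In classical monocyte-like cells Ccr2 stood at 566 ± 90.8 CPM in WT and 59.3 ± 68.6 CPM in CCR2KO, where 3 of 8 tags had no read (log2 change -3.43, SE 0.69, adjusted p = 0.00329). In interstitial macrophage-like cells it fell from 247 to 1.37 CPM, with a log2 change of -7.31 (SE 0.53, adjusted p = 1.321e-08). It also fell in cluster 11 (log2 change -4.90, SE 0.65, adjusted p = 0.001438, and 0.0594 at equal cell numbers), in cluster 3 (-5.24, adjusted p = 0.007345, and 0.2196 at resolution 0.8) and in dendritic cell cluster 17 (-4.50, adjusted p = 0.02895, and 0.06175 at equal cell numbers), where it passed in 12 of 17 fits with 1 tag left out. Ccr2 was lower in 5 of the 9 classes where it was tested. Among them cluster 3 is a fibroblast cluster, where reads from monocytes are not excluded as the source. Of monocyte-like cells, 53.7% had a Ccr2 read in WT and 6.51% in CCR2KO, at median depths of 26681 and 19628 reads. Of B cell-like cells, which should lack the receptor, 1.92% and 0.264% had one, at 12793 and 11519 reads. Ccr2 lies on chromosome 9 from 124101950 to 124113557 on the plus strand (GRCm38). The files do not say which part of the gene was deleted or which part the reads cover, so the low level checks the genotype labels only as far as the reads fall in the deleted part.

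**Figure D1:**
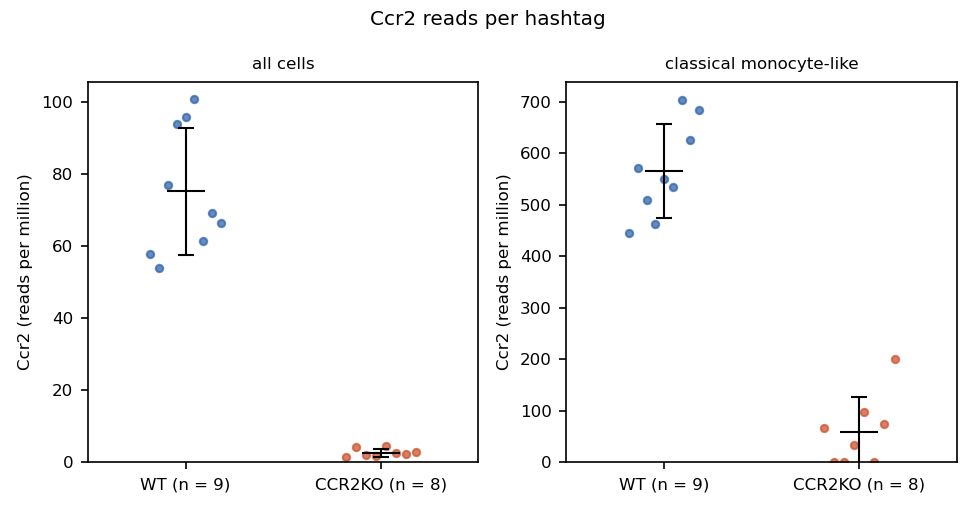
Ccr2 level in CPM per hashtag in WT and CCR2KO, over all cells and in classical monocyte-like cells; dots are tags, and the bar and whisker give mean and SD. Over all cells, each CCR2KO tag lies at or below 4.43 CPM and each WT tag at or above 53.9 CPM. This level also reflects the lower share of monocyte-like cells in CCR2KO.

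The second question was how the cell make-up of the silica-treated lung differs without the receptor. Monocytes and a macrophage cluster were depleted in CCR2KO, and surfactant-making epithelial cells were more frequent. Classical monocyte-like cells made up 6.84 ± 1.53% of WT cells (n = 9) and 1.14 ± 0.300% of CCR2KO cells (n = 8), 6.00-fold less, and no CCR2KO tag reached the lowest WT tag (1.60% against 5.10%). Cluster 11 was led by Mmp12, Gpnmb, Ccl24, Inhba, Arg1 and Spp1, genes of macrophages in injured or scarring tissue. It fell from 5.49 ± 3.01% to 0.982 ± 0.590%, with tags between 1.19 and 8.86% in WT and between 0.124 and 1.99% in CCR2KO. Dendritic cell cluster 17 also fell, from 2.25 ± 0.652% to 1.51 ± 0.364%. Alveolar type 2-like cells rose from 5.30 ± 1.16% to 10.1 ± 2.60%, and adventitial fibroblast-like cells from 2.29 ± 0.568% to 3.18 ± 0.612%. Shares are parts of a whole, so the fall of monocyte-like cells and cluster 11 alone raises the other shares to some degree. The adjusted p-values of the exact permutation test over tags were 0.00123 for monocyte-like cells, 0.00839 for cluster 11, 0.0447 for dendritic cell cluster 17, 0.00165 for alveolar type 2-like cells and 0.0354 for adventitial fibroblast-like cells.

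A further 3 small populations were higher in CCR2KO and nearly absent from the WT library. Mesothelial-like cells, which line the outer lung surface, counted 3 in WT and 89 in CCR2KO (0.0173 ± 0.0261% against 0.598 ± 0.169%, adjusted exact p = 0.00123). Plasma cell-like cells, which secrete antibodies, counted 5 and 56 (adjusted exact p = 0.00370). Macrophage cluster 30, led by Ctsk, Spp1, Marco, Fabp4 and Trem2, counted 14 and 100 (adjusted exact p = 0.0388). With 1 library per genotype, a cluster held almost wholly by 1 library may belong to that library and not to a cell type. With 1 tag left out, macrophage cluster 30 passed in 6 of 17 fits, dendritic cell cluster 17 in 5 and adventitial fibroblast-like cells in 8.

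The other 22 of the 30 populations tested did not pass in this unpaired test. With same-numbered tags as pairs, a setting chosen after seeing the data, interstitial macrophage-like, T cell-like, alveolar fibroblast-like and alveolar type 1-like cells and cluster 22 passed. Interstitial macrophage-like cells were 3.11 ± 1.20% and 1.93 ± 0.744% (adjusted exact p = 0.0896), and alveolar macrophage-like cells 4.93 ± 1.75% and 4.11 ± 1.09% (adjusted exact p = 0.372). Neutrophil-like cells were 6.00 ± 3.22% and 8.09 ± 2.77% (adjusted exact p = 0.253), and T cell-like cells 4.86 ± 2.42% and 6.56 ± 2.14% (adjusted exact p = 0.234). As a share of haematopoietic cells the T cell-like difference was 6.98 points (adjusted exact p = 0.00374). Monocyte-like cells and cluster 11, fewer in CCR2KO, are part of that denominator, and their fall alone raises the other shares of it. The differences of alveolar macrophage-like and neutrophil-like cells changed sign in another setting each. Alveolar fibroblast-like cells were 6.12 ± 2.87% and 6.83 ± 2.07% (adjusted exact p = 0.717), and cluster 3 was 6.02 ± 3.05% and 8.01 ± 2.65% (adjusted exact p = 0.252). Because genes that define clusters also differed between genotypes, the cells were clustered again without the 412 genes called in any class, a setting chosen after seeing the data. Monocyte-like cells were then 5.82% and 1.26% and cluster 11 was 6.72% and 1.06%, both still past the threshold, while adventitial fibroblast-like cells (adjusted exact p = 0.0630) and dendritic cell cluster 17 (adjusted exact p = 0.0524) no longer passed.

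**Figure D2:**
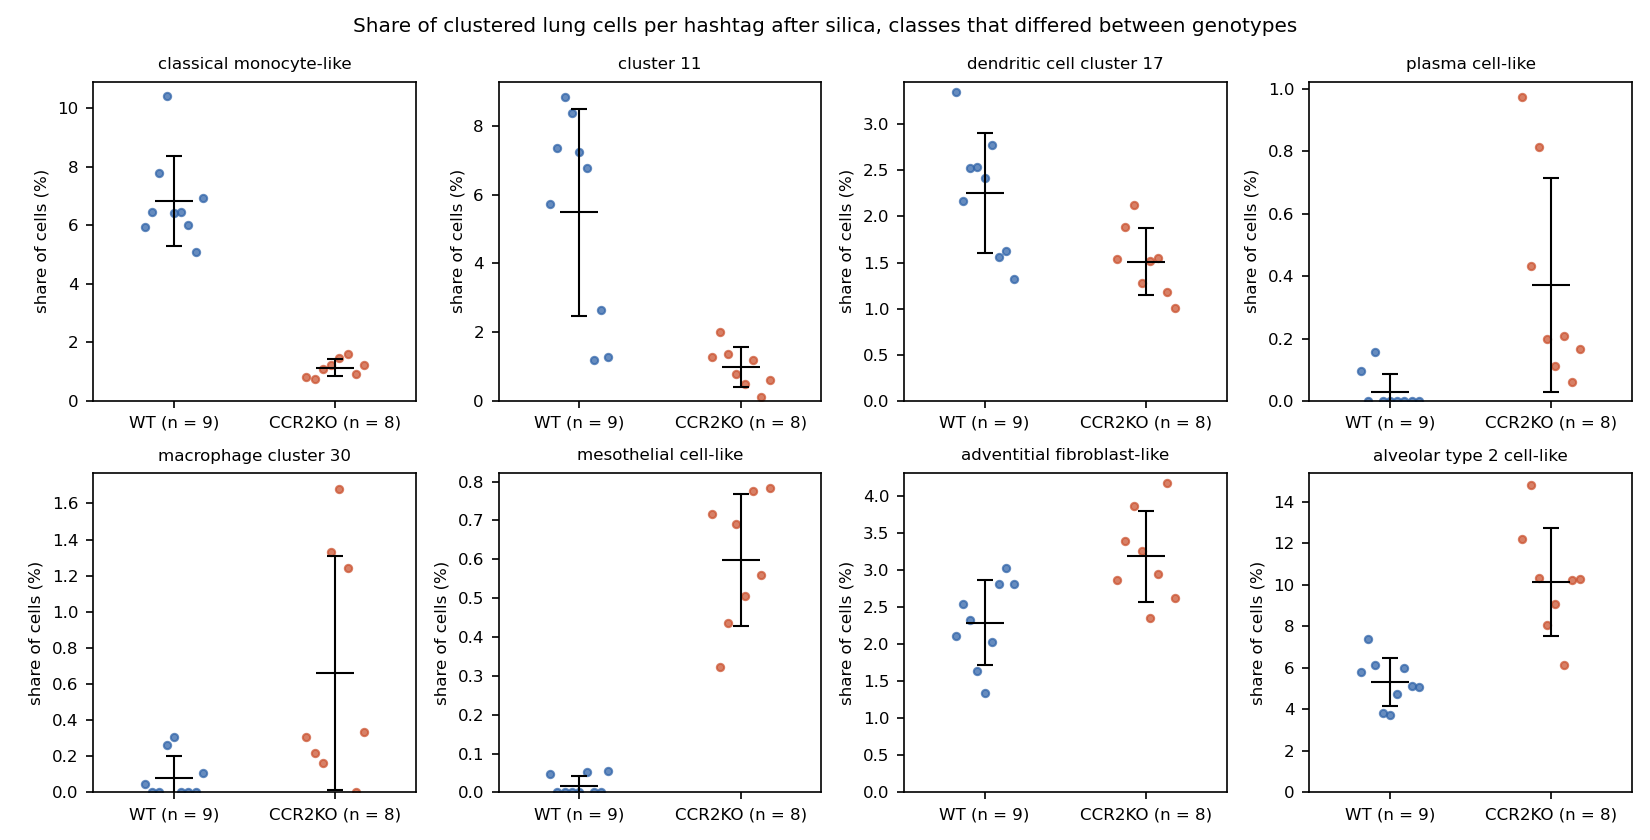
Share of all clustered cells per hashtag, in percent, for the 8 populations that differed between WT and CCR2KO; dots are tags, and the bar and whisker give mean and SD. Monocyte-like cells range from 5.10 to 10.4% in WT and from 0.754 to 1.60% in CCR2KO.

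The next question was how the cells of each population differ. The CCR2KO monocyte-like cells had more transcripts of the patrolling, nonclassical kind of monocyte, and less of Arg1 and Mrc1, of ferritin and of some interferon-induced genes. Nonclassical markers rose as a set: 3 of 8 measured members were higher over all genes and 7 when adjusted over the list alone, with a median log2 change of 1.18 (camera adjusted p = 1.209e-16, and adjusted p = 0.002472 with an estimated correlation). Classical markers fell, with 2 of 7 measured members lower over all genes and a median log2 change of -1.38 (camera adjusted p = 0.02378, and adjusted p = 0.1048 with an estimated correlation). The cluster's 100 leading genes held 7 classical and 4 nonclassical markers, so a different mix of both kinds within it is not excluded. Among the nonclassical markers was Spn, a sialoglycoprotein typical of nonclassical monocytes (110.2 against 436 CPM, log2 change 1.98, SE 0.37, adjusted p = 0.001708). Nr4a1, the transcription factor that nonclassical monocytes need, had a log2 change of 0.98 (adjusted p = 0.0112). Nr4a1 is also on the list of immediate early genes, which cell dissociation induces, so it counts in both lists. Other genes that rose were Cd36, a scavenger receptor for lipids (183 against 822 CPM, log2 change 2.17, adjusted p = 0.0008146), Cd300e (54.5 against 359.7 CPM, log2 change 2.72, adjusted p = 0.001074), the adhesion molecule Ceacam1 (log2 change 1.30, adjusted p = 0.00212) and Klf2, a factor of quiescence in circulating cells (log2 change 1.89, adjusted p = 0.01238).

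Arg1, the arginase of alternatively activated macrophages, fell from 96.9 to 4.17 CPM in monocyte-like cells (log2 change -4.61, SE 1.06, adjusted p = 0.01064), and the mannose receptor Mrc1 fell by 4.47 on the log2 scale. The elastase Mmp12 fell by 3.69 and the interleukin-6 family cytokine Osm by 1.46. Arg1 and Mmp12 lead cluster 11, whose share fell too, so reads from its cells are not excluded as the source. The list of type 2 and alternative activation as a whole went both ways, with 1 member higher (Ear2, log2 change 1.04), 2 lower, a median log2 change of -0.08, a mean of -0.79, a test direction of higher and a camera adjusted p of 0.7199. Of 14 genes of oxidative stress and metal handling 4 fell, among them the ferritin chains Fth1 (11680 against 5933 CPM, log2 change -0.98) and Ftl1 (log2 change -0.59) and the metal-binding Mt1 (log2 change -1.34); the list's camera adjusted p was 0.02728, and adjusted p = 0.06348 with an estimated correlation. Of 10 growth factors and ligands linked to fibrosis 1 fell and 4 did when adjusted over the list alone (camera adjusted p = 0.02728, and adjusted p = 0.08712 with an estimated correlation). Of 25 interferon response genes 3 fell, with a median log2 change of -1.54 (camera adjusted p = 5.926e-10, and adjusted p = 0.1405 with an estimated correlation); Ifi27l2a went from 2160.0 to 849 CPM and Oas1a fell by 2.06 on the log2 scale. The immediate early genes, which cell dissociation induces, had 3 of 16 members higher and a median log2 change of 0.19 (camera adjusted p = 7.211e-05, and adjusted p = 0.05849 with an estimated correlation). Surfactant genes of other cells, such as Sftpa1 (log2 change 1.90), were also higher, in 2 of 16 members.

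In all, 27 genes were higher and 260 lower among 8029 tested in monocyte-like cells. The excess of lower calls was absent at a mean of at least 100 CPM (56 higher, 42 lower) and with the size rule on pooled libraries, which has no test (1039 higher, 714 lower). At an equal depth of 5000 reads, CCR2KO monocyte-like cells had 652 detected genes against 831 in WT (exact permutation p = 8.22707e-05), so a lower yield of genes in this library goes along with the lower calls and the genes at 0. At 0 reads in all 8 CCR2KO tags were 12 of the named genes. They include the interferon-induced Mx2, 42.1-fold lower against the floor in reads, and Nlrc5, a regulator of MHC class I genes, 41.2-fold lower. By cells, 5.48% of WT cells held a read of Mx2 and 5.04% one of Nlrc5. The same floor counted in CCR2KO cells would be 1.78%. Mx2 was read in 63 of 1150 WT cells and in 0 of 169 CCR2KO cells, which were read less deeply. The number of calls depended on the cells and tags used. With WT cells drawn down to the CCR2KO number, 19 genes passed. Drawing down also removes cells and reads, so unequal numbers and lost power cannot be told apart. Without WT replicate 6 the number was 103, and without CCR2KO replicate 5 it was 531. Of the 287 genes called, 181 had no read in at least 4 of the 8 CCR2KO tags.

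In cluster 11, the Mmp12 and Gpnmb macrophages, few genes passed, and their number depended on the setting. The test used 137 CCR2KO cells. The 9 genes called became 39 with the strict cell filter (5 shared), 27 with every tagged cell (4 shared), 73 with doublets kept (8 shared), 106 at resolution 0.8 (5 shared) and 137 by DESeq2 (8 shared). Lpl, the lipase that takes up lipoprotein fat, rose from 640.1 to 1502 CPM (log2 change 1.23, SE 0.24, adjusted p = 0.03874), and Cxcl10, an interferon-induced chemokine for T cells, fell from 55.5 to 1.04 CPM (log2 change -5.43, SE 0.97, adjusted p = 0.0194). Arhgef10l, a guanine nucleotide exchange factor, was at 0 in every CCR2KO tag tested, 51.0-fold lower against a floor of 3 reads. By cells, 7.32% of WT cells held a read, and a floor of 3 CCR2KO cells would be 2.19%. Of 14 growth factors and ligands linked to fibrosis none passed over all genes or over the list alone (median log2 change -0.22, camera adjusted p = 0.9075). Of 23 lipid-associated and scar-associated macrophage genes 1 was higher (median log2 change 0.31, camera adjusted p = 0.09565), and Spp1, the matrix protein osteopontin, had a log2 change of 0.56 (adjusted p = 0.8901). Interferon response genes had a median log2 change of -0.78 with no member called over all genes (camera adjusted p = 4.439e-05, and adjusted p = 0.5306 with an estimated correlation); with 1 tag left out this median ranged from -1.95 (without CCR2KO replicate 2) to -0.53 (without CCR2KO replicate 4), and that of the lipid-associated list from 0.12 (without CCR2KO replicate 2) to 0.49 (without CCR2KO replicate 8), where it passed. In all, 3 genes were higher and 6 lower among 8906 tested, from 9 WT and 6 CCR2KO tags; on simulated data of this size 3% of 2-fold and 24% of 4-fold changes were recovered. A rise of Retnla (log2 change 7.24, adjusted p = 0.04793) came from 1 tag: without CCR2KO replicate 8 its log2 change was -0.58. Lpl passed in 6 of the 15 fits with 1 tag left out, and Cxcl10 in 12. At resolution 0.8 the direction of Cxcl10 reversed (log2 change 0.51, edgeR adjusted p = 0.871).

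Interstitial macrophage-like cells, the C1q-expressing macrophages outside the airspace, had higher levels of chemokines that CCR2 binds. Ccl2 rose from 880.4 to 2066 CPM (log2 change 1.23, SE 0.18, adjusted p = 0.0007862), Ccl7 from 725 to 1669 CPM (log2 change 1.20, adjusted p = 0.03061) and Ccl12 from 648 to 1422 CPM (log2 change 1.13, adjusted p = 0.03061). Ccl8 had a log2 change of 1.14 (adjusted p = 0.4095). As a list, the 4 ligands rose, with 3 members higher over all genes and 4 adjusted over the list alone (camera adjusted p = 2.186e-11, and adjusted p = 0.00278 with an estimated correlation). Also higher were Ch25h, which makes an oxysterol (log2 change 2.36), Mfge8, which helps the uptake of dying cells (log2 change 2.08), and Nfkbiz, a regulator of inflammatory transcription (log2 change 0.91). Monocyte genes fell: Plac8 (log2 change -3.14, adjusted p = 0.0003469) and Ms4a4c (log2 change -2.98, adjusted p = 0.0005606) were lower, and 3 of 7 monocyte markers passed (camera adjusted p = 1.245e-11, and adjusted p = 0.0001025 with an estimated correlation). So were Thbs1, which encodes thrombospondin, an activator of latent TGF-beta (616 against 89.5 CPM, log2 change -2.80, SE 0.47, adjusted p = 0.003261), and the angiogenic factor Vegfa (114 against 21.2 CPM, log2 change -2.44, adjusted p = 0.01046). Nr4a2 (log2 change -1.64) and the cell cycle inhibitor Cdkn1a (log2 change -1.14) fell as well. Of 20 C1q and interstitial macrophage genes none passed over all genes (median log2 change 0.37, camera adjusted p = 0.0004294, and adjusted p = 0.3062 with an estimated correlation). Because Ccr2 and monocyte markers fell in the same population, a different mix of cells within it is not excluded, for the higher and the lower genes.

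In all, 12 genes were higher and 29 lower among 9763 tested in interstitial macrophage-like cells. Immunoglobulin and plasma cell transcripts were among the higher ones, with 3 of 10 members of the immunoglobulin list (camera adjusted p = 1.245e-11, and adjusted p = 0.00278 with an estimated correlation) and Jchain (log2 change 8.18). Ccl2, Thbs1, Vegfa, Plac8 and Ms4a4c passed in all 17 fits with 1 tag left out, while Ccl7 passed in 6, Ccl12 in 5, Ch25h in 9 and Mfge8 in 6. With WT cells drawn down to equal numbers, 27 genes passed.

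Alveolar macrophage-like cells, the macrophages of the airspace, differed in few genes. Among the higher genes were the immunoglobulin-like receptor Pira1 (log2 change 1.29, adjusted p = 0.008212) and Fkbp5, a glucocorticoid target (log2 change 0.96, adjusted p = 0.03825). Lower were Lypla2 (log2 change -1.44), the adhesion molecule Cd99 (log2 change -1.03), Gas7 (log2 change -0.88) and Wfdc21 (log2 change -0.65). Lypla2 lay below 0 in 25 of 25 populations and Cd99 in 24 of 25, so neither shift was particular to this population. Of 24 cell cycle genes none passed over all genes, with a median log2 change of 0.39 (camera adjusted p = 2.118e-06, and adjusted p = 0.4728 with an estimated correlation). Of 21 interferon response genes none passed (median log2 change -0.51, camera adjusted p = 1.811e-08, and adjusted p = 0.3813 with an estimated correlation), and classical monocyte markers fell beside them (median log2 change -1.60, camera adjusted p = 1.725e-05, and adjusted p = 0.08143 with an estimated correlation). In all, 5 genes were higher and 16 lower among 10966 tested. Pira1, Lypla2 and Cd99 passed in all 17 fits with 1 tag left out, while Fkbp5 passed in 6, Wfdc21 in 5 and Gas7 in 4.

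Alveolar type 2-like cells were more frequent in CCR2KO, and their surfactant genes did not pass the test. Of 18 surfactant and lipid synthesis genes none passed over all genes or over the list alone (median log2 change 0.09, camera adjusted p = 0.2719). Of 18 genes of reactive and transitional epithelium, the state that injured type 2 cells pass through, none passed over all genes (median log2 change -0.30, camera adjusted p = 0.1187). Lower were Lypla2 (log2 change -1.91), Cdc42bpg (log2 change -1.46), the actin-binding Cotl1 (log2 change -1.37), Cd99 (log2 change -1.11) and Ptms (log2 change -0.77). These shifts were not particular to type 2-like cells. Lypla2 lay below 0 in 25 of 25 populations, Cdc42bpg in 20 of 20, Cd99 in 24 of 25, and Cotl1 and Ptms in 23 of 25. Of the 14 genes called, 0 were called in type 2-like cells alone. The 1 higher gene was the antibody chain Igha, with a log2 change of 4.58 (adjusted p = 1.811e-06), a product of plasma cells and not of epithelium. Cell cycle genes had a median log2 change of 0.77 with none of 23 called (camera adjusted p = 7.969e-09, and adjusted p = 0.1419 with an estimated correlation). In all, 1 gene was higher and 13 lower among 11565 tested. Lypla2, Cdc42bpg, Cd99 and Ptms passed in all 17 fits with 1 tag left out, while Cotl1 passed in 5.

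Among fibroblasts, the question was whether matrix genes differ without the receptor. Collagen and matrix genes did not pass as a list in any of the 3 fibroblast populations. In alveolar fibroblast-like cells none of 26 members passed (median log2 change 0.06, camera adjusted p = 0.8195), and elastin, Eln, had a log2 change of -0.96 (adjusted p = 0.08269). In adventitial fibroblast-like cells none of 30 passed (median log2 change 0.09, camera adjusted p = 0.1957). In cluster 3, a fibroblast cluster led by Nrep, Tnc, Fst, Sfrp1 and Col1a1, none of 30 passed (median log2 change 0.06, camera adjusted p = 0.4116). The edgeR test at an unadjusted p under 0.05 gave 705, 864 and 879 genes in these populations, over all genes tested.

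Single genes did differ in fibroblasts. In adventitial fibroblast-like cells the matrix protein Cilp rose from 40.3 to 153 CPM (log2 change 1.92, SE 0.33, adjusted p = 0.003361), as did the actin-severing Gsn (5913 against 9060.0 CPM, log2 change 0.62, adjusted p = 0.0006325), the complement genes C4a (log2 change 0.81) and C4b (log2 change 0.74, adjusted p = 0.006673), the TGF-beta receptor Tgfbr2 (log2 change 0.56, adjusted p = 0.03252) and the TGF-beta target Ctgf (log2 change 0.95, adjusted p = 0.04739). C4b rose in alveolar fibroblast-like cells too (log2 change 0.64, adjusted p = 0.02066). Herpud1, a gene of the endoplasmic reticulum stress response, rose in alveolar (log2 change 1.48, adjusted p = 0.001472) and adventitial fibroblast-like cells (log2 change 0.99). Pwwp2a, a chromatin protein, fell in all 3 populations, with log2 changes of -1.95, -3.87 and -1.37. Herpud1 lay above 0 in 23 of 25 populations, so its direction was not particular to fibroblasts. Pwwp2a lay below 0 in 22 of 25, with a median log2 change of -0.394, and was called in these 3 alone. In alveolar fibroblast-like cells Hdac3 rose (log2 change 2.59) and Ucp2 fell (log2 change -2.64). In cluster 3 the interferon-induced Xaf1 fell from 131 to 51.3 CPM (log2 change -1.35, SE 0.24, adjusted p = 0.01543), and 1 of 25 interferon response genes passed over all genes and 14 adjusted over the list alone (median log2 change -1.26, camera adjusted p = 5.659e-27, and adjusted p = 0.07349 with an estimated correlation). Genes of MHC class II presentation were lower as a list in alveolar fibroblast-like cells, where 5 of 7 passed adjusted over the list alone (median log2 change -1.24, camera adjusted p = 4.633e-07, and adjusted p = 0.04188 with an estimated correlation), and in cluster 3 (camera adjusted p = 1.361e-09, and adjusted p = 0.07349 with an estimated correlation).

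Single genes known from myeloid cells were lower as well. Classical monocyte markers fell as a list in adventitial fibroblast-like cells (median log2 change -0.73, camera adjusted p = 0.02203, and adjusted p = 0.212 with an estimated correlation) and in cluster 3 (median log2 change -0.67, camera adjusted p = 0.02041, and adjusted p = 0.1069 with an estimated correlation). Ctss (log2 change -2.80), Ccl9 (-3.88) and Chil3 (-1.55) fell in adventitial fibroblast-like cells, and Clec7a (-3.25), Fcer1g (-2.19) and Tyrobp (-2.16) in cluster 3. In all, 12 genes were higher and 22 lower among 10735 tested in alveolar fibroblast-like cells, 11 and 45 among 10384 in adventitial ones, and 3 and 22 among 12126 in cluster 3. Of the genes named, Ctgf passed in 4 of the 17 fits with 1 tag left out, Tgfbr2 in 9, Ucp2 in 3, Tyrobp in 3, Fcer1g in 4, Ctss in 9, Chil3 in 5, Clec7a in 13 and Ccl9 in 16, while Cilp, Gsn, C4a, Herpud1, Pwwp2a and Xaf1 passed in all 17.

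In neutrophil-like cells, held by clusters 6 and 18, the interferon response was lower as a list and no inflammatory gene passed. Ifitm3, an interferon-induced membrane protein, fell from 1393 to 583 CPM (log2 change -1.26, adjusted p = 0.01533), and the survival kinase Pim1 from 2343 to 1223 CPM (log2 change -0.94, adjusted p = 0.004189). Ifitm3 and Pim1 each lay below 0 in 24 of 25 populations, so neither direction was particular to neutrophil-like cells. Of 22 interferon response genes none passed over all genes and 5 did adjusted over the list alone (median log2 change -1.27, camera adjusted p = 1.268e-20, and adjusted p = 0.04146 with an estimated correlation). Classical monocyte markers fell beside them (median log2 change -1.36, camera adjusted p = 1.173e-05, and adjusted p = 0.005221 with an estimated correlation). Of 16 inflammatory cytokine and inflammasome genes none passed either way (median log2 change -0.12, camera adjusted p = 0.5194). In all, 1 gene was higher and 5 lower among 6627 tested.

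T cell-like cells, held by clusters 9 and 20, differed in few genes. Btg1, an antiproliferative gene, had a log2 change of 0.46 (adjusted p = 0.03066), Ctnnbl1 of 3.28 (adjusted p = 0.02301) and Cd99 of -1.47. Of 11 cytotoxic genes none passed (median log2 change -0.03, mean 0.14, test direction higher, camera adjusted p = 0.7277), and none of 15 genes of activation and regulatory T cells did (median log2 change -0.10, test direction higher, camera adjusted p = 0.8494). Of 20 interferon response genes none passed over all genes (median log2 change -0.66, camera adjusted p = 0.0006856, and adjusted p = 0.3525 with an estimated correlation). In all, 4 genes were higher and 10 lower among 8723 tested. Ctnnbl1 passed in 10 of the 17 fits with 1 tag left out and Btg1 in 7.

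Across populations, the interferon response was lower in CCR2KO in most of the 10 described. The mean log2 level of the list per tag, over all cells, was 5.80 ± 0.508 in WT (n = 9) and 4.66 ± 0.630 in CCR2KO (n = 8, exact permutation p = 0.00181). This level also reflects the cell make-up, since monocyte-like cells, at a level of 6.89 in WT, were fewer in CCR2KO. Genes at 0 reads lower such a mean, and fewer genes were detected in CCR2KO at equal depth in each population measured. The adjusted p of the exact permutation test, over 10 populations, was 0.00658 in monocyte-like cells, 0.0107 in neutrophil-like cells, 0.0134 in interstitial macrophage-like cells and in cluster 3, 0.0424 in cluster 11 and 0.0491 in alveolar fibroblast-like cells. It was 0.0584 in alveolar macrophage-like cells, 0.0861 in adventitial fibroblast-like cells and 0.255 in both alveolar type 2-like and T cell-like cells. Whether the difference varies between populations was not tested.

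**Figure D3:**
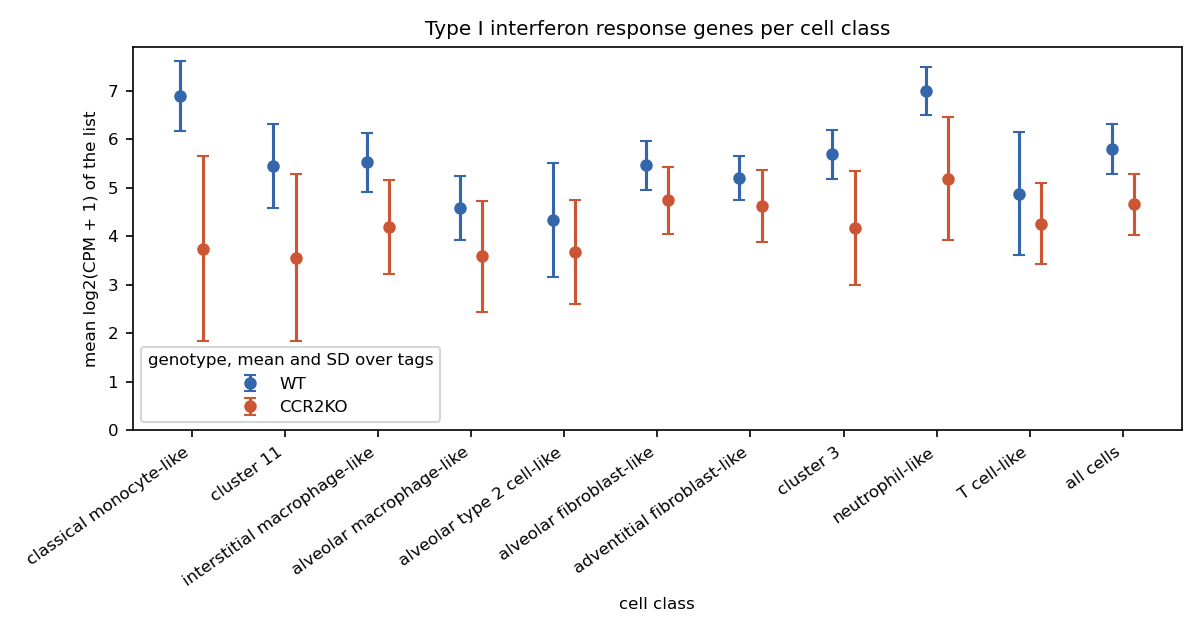
Mean log2(CPM + 1) of the interferon response genes per population, as mean and SD over hashtags, in WT and CCR2KO. Monocyte-like cells lie at 6.89 in WT and 3.74 in CCR2KO, where tags held 14 to 31 cells against 91 to 197 in WT; genes at 0 reads lower this mean.

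Some genes were called in populations of several lineages. The ribosomal RNA transcripts Rn45s, Rn28s1 and Rn18s were lower in 19, 18 and 14 of 25 populations, and Rps29, a ribosomal protein gene, in 17. Cd99 was lower in 9 and Ifitm3 in 6. Igha was higher in 12 populations and the club cell secretoglobin Scgb1a1 in 4, though neither is a product of most of them. Of the 412 genes called in at least 1 population, 350 were called in 1 alone, and 2 went in opposite directions in different populations. The edgeR test on all cells together called 956 genes higher and 1184 lower among 19190, a comparison that also reflects the change in cell make-up. In the 15 populations not described above, 29 calls were higher and 83 lower; alveolar type 1-like cells had none in edgeR, with 284 genes at an unadjusted p under 0.05 and 6 called by DESeq2.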

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

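The comparisons of marker lists with cell shares, of interferon levels with 1 tag left out, of Igha reads in populations other than type 2-like cells, of the spread of interferon reads over tags, and of other splits of the tags were chosen after the results were seen; the other tests of this part were written down before. Of 36 groups of tags examined, 1 held a value far from the rest, where chance gives about 1 in 20. Alveolar fibroblast-like cells made up 11.4% of CCR2KO tag 7, against a median of 6.17% in the other CCR2KO tags. WT tag 7 had 11.2%, the highest share among the WT tags. Among the cells that the authors named doublet, which entered no comparison, Ccr2 stood at 62.5 CPM in the 680 WT cells and at 0.859 CPM in the 531 CCR2KO cells.

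Interferon response genes were lower in CCR2KO as a list in macrophages, neutrophils and fibroblasts as well as in monocytes, with the preset correlation. With an estimated correlation the list passed in neutrophil-like cells (adjusted p = 0.04146) and in none of the other 9 described populations (0.07349 in cluster 3 to 0.5306 in cluster 11). Over tags, alveolar macrophage-like (adjusted exact p = 0.0584), adventitial fibroblast-like (0.0861), type 2-like and T cell-like cells (both 0.255) did not pass. Free RNA of the monocytes that CCR2KO lacks would lower interferon and monocyte transcripts in the ratio they have in WT monocytes. In 7 of the 9 other described populations the interferon reads were lower by over 3 times that ratio, or lower with no fall of the monocyte markers (alveolar fibroblast-like cells). Beyond the spread over tags this held in 2, cluster 3 and alveolar fibroblast-like cells. There the 95% lower bound of the excess was 608 and 90.9 CPM. The summed monocyte markers were 1058 CPM in WT and 775 CPM in CCR2KO in cluster 3. In alveolar fibroblast-like cells they were 402 and 423 CPM. Marker reads made by the fibroblasts themselves would hide a fall of monocyte RNA, so the test cannot decide there. In the others, whose bounds span 0, monocyte RNA as a cause stays open too. No single tag carried the difference over all cells, where the highest exact permutation p with 1 tag left out was 0.00384615. The level over all cells also reflects the change in cell make-up. Each genotype had 1 cartridge, so an effect of genotype cannot be told apart from one of cartridge, and whether losing the receptor lowers interferon signalling in the silica-treated lung stays a hypothesis.

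Transcripts of antibody-secreting cells and type 2 cells were higher in unrelated CCR2KO populations, and those of monocytes lower. Free RNA that follows the cell make-up of each library may contribute: for 3 of 4 marker lists the median log2 change in other lineages had the sign of the change in share, with monocyte markers at -0.52, type 2 markers at 0.33 and plasma cell markers at 1.80. The mesothelial list, with 2 markers measured, was at -0.02 and leaves this open. Undetected doublets with plasma cells would put the antibody reads in few cells, and 27.9% of the CCR2KO type 2-like cells held 90% of their Igha reads, which argues against it there. In CCR2KO neutrophil-like, alveolar fibroblast-like and T cell-like cells 7.41%, 12.5% and 13.5% held as much, so doublets stay open for them. A reading of Igha, Scgb1a1 or Sftpa1 as regulated in cells that do not make them is therefore not warranted.

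Ribosomal RNA and ribosomal protein transcripts were lower across lineages in CCR2KO, with 91 of 98 ribosomal protein genes below 0 over all cells. If lower read depth per cell in the CCR2KO library were the cause, the difference was predicted to end at equal depth. Rn45s was still called lower in 8 of the 10 described populations with cells thinned to 5000 reads. Random thinning leaves the expected share of each gene unchanged, so this test cannot decide on depth. In it, 174 CCR2KO cells and 0 WT cells were too shallow to thin and were left out. Poorer recovery of short transcripts in 1 library stays open: other short genes lay at -0.171 against longer ones (95% bounds -0.222 and -0.105), near the limit of 0.2 set beforehand. Short and long ribosomal protein genes had alike medians (-0.128 and -0.129). Length was that of a gene's longest annotated transcript, and 15 of 98 ribosomal protein genes counted as short. A gene counted as long may be read from a shorter transcript, so these medians cannot decide. Genotype against cartridge, with 1 cartridge each, could not be tested, so no biological reading is offered.

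Chance in how tags fall into groups was tested by 30 splits of the tags into the same sizes, the real one included; a first run had more splits, and their number was lowered for its run time. For the gene counts of each described population and of the other 15 together, 1 split of 30, the real one, gave as many genes. That is the smallest share that 30 splits allow, with no adjustment over these counts. The other splits mix both genotypes in each group, so a difference between the libraries widens the spread within groups and lowers their counts. Chance is therefore not excluded by these splits. The real counts were 287 in monocyte-like cells, 9 in cluster 11, 41 in interstitial macrophage-like cells, 56 in adventitial fibroblast-like cells, 25 in cluster 3, 6 in neutrophil-like cells and 14 in T cell-like cells, each with a highest other of 0. They were 21 in alveolar macrophage-like, 14 in alveolar type 2-like and 34 in alveolar fibroblast-like cells, with a highest other of 1, and 112 in the other 15, with 4. These splits say nothing on cartridge, which parts the tags as genotype does.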

How the results depend on the processing

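The size rules on pooled libraries, equal cell numbers, DESeq2 size factors in edgeR, the tags present in both libraries, the clustering without called genes, and same-numbered tags as pairs for shares were chosen after seeing the data. The cause of a change named here was not tested unless the setting itself shows it. Comparisons by day and the alternatives without day 3, 7 or 21 were not run, since no tag could be given a day, and a size threshold cannot be applied to the list test. Simulated 2-fold changes were recovered in 1% of cases in monocyte-like cells, 3% in cluster 11 and 4% in both neutrophil-like and T cell-like cells.

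The shares of monocyte-like, type 2-like, mesothelial-like and plasma cell-like cells, of cluster 11 and of macrophage cluster 30 kept direction and side of the threshold in every setting that gave a value, apart from tags left out. The adventitial fibroblast-like rise no longer passed with every tagged cell (0.774 points), at resolution 0.8 (0.762) and 2.5 (0.727), with fewer clustering genes (0.699), with another seed (2.06) and without the called genes (0.686). The fall of dendritic cell cluster 17 no longer passed with the strict cell filter (-0.642 points), at resolution 0.8 (-0.746) and 2.5 (-0.730), with fewer genes (-0.716), another seed (-0.737) and without the called genes (-0.724). With haematopoietic cells as denominator, T cell-like cells passed (6.98 points, adjusted exact p = 0.00374) and alveolar macrophage-like cells reversed (0.285 points). That denominator includes the monocyte-like cells and cluster 11, whose fall alone raises the other shares of it. Neutrophil-like cells reversed with the strict filter (-0.469 points).

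With 1 tag left out, the adventitial difference ranged from 0.753 to 1.01 points (passing in 8 of 17 fits), that of dendritic cell cluster 17 from -0.862 to -0.608 (5 of 17) and that of macrophage cluster 30 from 0.432 to 0.672 (6 of 17). Interstitial macrophage-like cells ranged from -1.38 to -0.914 points and passed without WT replicate 9. Gene counts ranged from 103 to 531 in monocyte-like cells (without WT replicate 6 and without CCR2KO replicate 5), from 20 to 50 in interstitial macrophage-like cells (without WT replicate 4 and CCR2KO replicate 6), from 19 to 39 in alveolar fibroblast-like cells (without WT replicates 2 and 5), from 6 to 10 in neutrophil-like cells and from 64 to 115 in the other 15 populations.

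Counts of genes called moved by over 1.5 times as follows, for monocyte-like cells (287), cluster 11 (9), interstitial macrophage-like (41), alveolar macrophage-like (21), type 2-like (14), alveolar fibroblast-like (34), adventitial fibroblast-like cells (56), cluster 3 (25), neutrophil-like (6), T cell-like cells (14) and the other 15 (112). DESeq2 called more in each, in that order 854, 137, 153, 112, 96, 112, 245, 130, 41, 39 and 714. So did the size rule on pooled libraries, with no test, at a pseudocount of 1 (1753, 788, 418, 70, 59, 220, 327, 141, 780, 572 and 18227) and of 5 (1461, 566, 275, 46, 33, 127, 198, 92, 541, 365 and 14269). A mean of at least 100 CPM tests fewer genes and gave 98, 4, 91, 60, 38, 60, 185, 61 and 13 in all but T cell-like cells, and 258 in the other 15. In monocyte-like cells these were 56 higher and 42 lower, and those of the size rule with a pseudocount of 1 were 1039 and 714, against 27 and 260. A size of at least 1 left 26 in interstitial and 9 in alveolar macrophage-like, 6 in type 2-like, 17 in alveolar and 11 in adventitial fibroblast-like cells, 16 in cluster 3, 3 in neutrophil-like and 6 in T cell-like cells and 48 in the other 15; a size of 0.58 left 32 in adventitial fibroblast-like and 9 in T cell-like cells.

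The strict cell filter gave 185 in monocyte-like cells, 39 in cluster 11, 8 in type 2-like cells, 48 in cluster 3 and 55 in the other 15. Every tagged cell gave 27 in cluster 11 and 69 in alveolar fibroblast-like cells. Keeping Scrublet's doublets gave 73 in cluster 11 and 177 in adventitial fibroblast-like cells. Resolution 0.8 gave 106 in cluster 11, 35 in alveolar macrophage-like cells and 47 in cluster 3, and resolution 2.5 gave 56 in alveolar fibroblast-like cells. Cells thinned to 5000 reads gave 139 in monocyte-like cells, 4 in cluster 11, 13 in alveolar macrophage-like cells, 10 in cluster 3 and 9 in T cell-like cells. No filter on low counts gave 655 in monocyte-like cells and 1435 in the other 15. Equal cell numbers gave 19, 2 and 27 in monocyte-like cells, cluster 11 and interstitial macrophage-like cells, and the tags of both libraries gave 117 in monocyte-like cells.

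Numbers of tags were not taken as pairs, a decision made on log2 shares before any blocked calls were seen: 7 of 8 same-numbered tags deviated together (correlations -0.148 to 0.825), and 4 CCR2KO and 4 WT tags correlated best with their own number. Shares in percent and in SD units gave 8 of 8 over 0.1, and CPM of all cells 6 of 8. With the tag number as a replicate block, the counts were 279 in monocyte-like cells, 4 in cluster 11, 27 in interstitial and 36 in alveolar macrophage-like, 25 in type 2-like, 28 in alveolar and 43 in adventitial fibroblast-like cells, 48 in cluster 3, 7 in neutrophil-like and 10 in T cell-like cells. Ccr2 in cluster 11 was -4.61 with the block (adjusted p = 0.0548) and -4.85 at equal cell numbers (adjusted p = 0.0594). Ccr2 in dendritic cell cluster 17 was -4.23 at equal cell numbers (adjusted p = 0.06175). With 1 tag left out it ranged there from -6.64 (without CCR2KO replicate 2) to -4.30 (without CCR2KO replicate 6), and did not pass without CCR2KO replicate 1 or 4 or WT replicate 3, 4 or 7 (highest adjusted p 0.06312). Ccr2 in cluster 3 was -3.40 at resolution 0.8 (adjusted p = 0.2196), and several settings, the block among them, could not test it there. Over all cells, in monocyte-like cells and in interstitial macrophage-like cells Ccr2 passed in each setting that tested it. With same-numbered tags as pairs (8 pairs, exact sign flips), T cell-like cells (1.34 points, adjusted exact p = 0.0260), alveolar fibroblast-like cells (1.20 points, 0.0361) and interstitial macrophage-like cells (-1.38 points, 0.0260) passed. So did cluster 22 (0.980 points, 0.0260) and alveolar type 1-like cells (0.868 points, 0.0361), and no other share changed its call. Without pairs on these tags, interstitial macrophage-like cells passed (0.0396), and T cell-like (0.363) and alveolar fibroblast-like cells (0.440) did not. Of 135 named genes, 91 passed with the block.

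The collagen list in cluster 3, which did not pass, reversed to -0.04 in thinned cells and lay at -0.01 without WT replicate 8. Retnla in cluster 11 reversed with the strict filter (-1.08), with every tagged cell (-0.051), with doublets kept (-0.997) and without CCR2KO replicate 8 (-0.58, the low end of a range to 7.52 with 1 tag left out), and Cxcl10 there at resolution 0.8 (0.51). No other named gene, and none of the other lists followed, reversed in a setting that was run; all 138 named genes tested by DESeq2 passed, and 75 of 117 did in thinned cells. DESeq2 size factors in edgeR moved the split of higher and lower calls to 68 and 185 in monocyte-like cells (from 27 and 260) and to 17 and 24 in interstitial macrophage-like cells (from 12 and 29). Library totals, and totals without mitochondrial and ribosomal genes, gave 3 and 10 in cluster 11 (from 3 and 6), and 7 and 16, and 8 and 16, in general capillary-like cells (from 12 and 15). In cluster 22 (12 and 13) totals without mitochondrial and ribosomal genes gave 12 and 25, and DESeq2 size factors 9 and 6.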

Other observations

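Other populations differed in a few genes of known function. Cluster 22, a stromal cluster led by Saa1, Saa3, Mt2, Timp1 and Il6, had higher Ptgs2, the inducible prostaglandin synthase (78.8 against 413.9 CPM, log2 change 2.39, SE 0.36, adjusted p = 0.00398), and higher complement C3 (log2 change 1.35, adjusted p = 0.003058) and C4b (230.3 against 652.3 CPM, adjusted p = 0.02596). Thbs1, lower in interstitial macrophage-like cells, was higher here (log2 change 1.03, adjusted p = 0.005946), and Nr4a1 was too (log2 change 1.31). The cytokine Mif was lower (log2 change -1.68, adjusted p = 0.04125). In all, 12 genes were higher and 13 lower, from 4 WT and 8 CCR2KO tags. The 4 WT tags were those with at least 10 cells of this cluster. The highest WT shares of it (2.19, 2.02 and 1.87%) lay in tags with neighbouring numbers. No tag could be given a day, so the WT and CCR2KO tags compared may differ in day. With the strict cell filter edgeR called none of 8814 genes in this cluster, with 376 at an unadjusted p under 0.05.

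Dendritic cell cluster 17 had lower Csf1r, the receptor for the macrophage growth factor (171 against 54.7 CPM, log2 change -1.65, SE 0.33, adjusted p = 0.0298), and lower Ifitm3 (log2 change -1.33, adjusted p = 0.002641). The monocyte markers fell there as a list (median log2 change -1.21, camera adjusted p = 6.957e-05, and adjusted p = 0.01276 with an estimated correlation). Tuba1b, a tubulin of dividing cells, was higher (log2 change 0.87, adjusted p = 0.00451), and none of 22 cell cycle genes passed (median log2 change 0.70, camera adjusted p = 8.757e-10, and adjusted p = 0.06581 with an estimated correlation). General capillary-like endothelium, held by clusters 0 and 5, had higher S1pr1, the sphingosine receptor that keeps vessels tight (log2 change 0.44, adjusted p = 0.04022), and Mcam (log2 change 0.73, adjusted p = 0.01343), beside a rise of type 2 cell markers as a list (median log2 change 1.07, adjusted p = 0.007867 with an estimated correlation). In smooth muscle-like cells the interferon list fell with both forms of the test (median log2 change -1.52, camera adjusted p = 3.353e-08, and adjusted p = 0.002393 with an estimated correlation). In club cell-like cells Gp2 was at 0 in the 78 WT cells used and 196-fold higher in CCR2KO against the floor in reads. By cells, 16 of 169 CCR2KO cells (9.47%) held a read, and the same floor counted in WT cells would be 3.85%.

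Tags with neighbouring numbers had like values, and no label explains this. Over all cells, the mean log2 level of the interferon list was 6.09, 6.03, 6.36, 6.18, 5.81, 6.22, 5.16, 4.98 and 5.35 in WT tags 1 to 9, and 5.05, 5.49, 5.55, 4.42, 4.30, 4.36, 3.81 and 4.27 in CCR2KO tags 1 to 8. The tags were not grouped by these values.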
